A study of Mus musculus with 6 samples.

How the data were processed

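The data were bulk RNA-seq of 6 samples of cultured mouse cells, 3 with rTSP1 and 3 with rTSP1 plus an antibody that neutralizes CD36. Per the labels' protocols, cells were sorted into a lysis reagent after 11 days of culture and libraries were made from 2 ng of total RNA with a full-length cDNA amplification kit. The labels call the sorted cells hematopoietic stem cells in one place and stem and progenitor cells in another. The treatment tags of the 3 rTSP1 samples read rThbs1, rThbs2 and rThbs3, where the last 2 are names of other thrombospondins, and the titles of all 6 samples, by which they were grouped, name rTSP1. Whether the tags are wrong was not settled.

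The authors deposited FPKM values, fragments scaled by transcript length and by the library's mapped fragments, with 2 decimals, in a table of 20696 genes, of which 2347 were at 0 in all libraries. The submitters' processing notes name FastQC 0.11.5, STAR and edgeR, and the builds GRCm38 and mm10. The aligner settings and the gene annotation are not given in the sources used here, nor is whether counting used strand, so overlapping and antisense genes cannot be told apart. FPKM divides by gene length and depth, so a few abundant transcripts lower all other values. The RNA gene Gm23935 took 12.6% to 16.0% of each library's FPKM total. That is a share of values scaled by length, and the gene's share of the fragments was not computed. It was not settled whether the submitters' normalization factors are part of the deposited FPKM values. Amplification from little RNA adds noise to low genes.

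Gene coordinates and lengths came from GENCODE M21 (GRCm38), which holds 20688 of the identifiers. Values of short genes multiplied by union exon length fell on whole multiples of what 1 read is worth: 98.1% to 98.9% of the low values examined were whole within a tolerance of 0.02 reads, where chance gives at most 15.8%. From that step the depth was estimated at 16100000 to 29400000 fragments per library. Reads without molecular identifiers are not independent molecules.

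Values were tested as log2(FPKM + 1), a pseudocount of 1, in genes with a mean of at least 1 FPKM over the 6 libraries, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, Benjamini-Hochberg adjusted p below 0.05). Lists were tested with camera at a preset correlation of 0.01 between genes and its default of 1 prior variance, adjusted over the 22 lists with at least 5 measured genes out of 24 fixed lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, stood beside it. The test, the lists, the rule for naming genes and 20 alternatives were set before the data were examined. The camera setting for the variance was not written down then. Its default was run first and is the one reported, and camera with a variance trend is given as an added alternative. A first matching of older symbols had joined Camp to Vamp5 and Bcl11b to Rit1; this was corrected after results had been seen, and a symbol now counts as an older name only if no gene currently bears it. With that rule Gucy1a3 and Gucy1b3 were matched to Gucy1a1 and Gucy1b1.

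Named genes were Cd36, Thbs1 and Cd47; the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups did not overlap, without predicted genes, pseudogenes and Riken clones; and up to 4 members of each list with the smallest unadjusted p. Others named in the text, such as Trp53, Gfi1, Hlf, Procr, Slamf1, Prss34 and Gata2, were chosen after their values were seen. Alternatives were other pseudocounts, filters, scalings and variance models, a replicate block, leaving out each library, other list tests and limma-voom on reads rebuilt from FPKM, the last chosen after seeing the data. A smooth trend on length, GC content and expression was fitted with mgcv 1.9.3.

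The tests were tried on simulated data of 10687 genes for this comparison. Of genes changed 1.5-fold, 40 of 70 were recovered (57.1%), of those changed 2-fold 65 of 67 (97.0%) and of those changed 4-fold 55 of 55, with 18 false calls among 10455 unchanged genes. All simulated genes had the same biological coefficient of variation, 11.05%, and varied independently. Real genes differ in spread and vary together, so these shares may not hold for them.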

Results

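RNA was sequenced from mouse hematopoietic stem and progenitor cells that had been expanded outside the body for 11 days. The starting cells were hematopoietic stem cells from the bone marrow of mice aged 4 months. The medium was based on polyvinyl alcohol and held 10 ng/mL stem cell factor and 100 ng/mL thrombopoietin, the cytokines used to keep such cells dividing. By the titles the cells of all 6 samples also received recombinant thrombospondin-1 (rTSP1), the protein product of Thbs1. The treatment tags of 2 rTSP1 samples, however, name other thrombospondins. In 3 of the 6 samples an antibody that neutralizes CD36, a cell surface receptor for thrombospondin-1 and a carrier of fatty acids, was added. The comparison asks how blocking CD36 changes transcript levels in cells exposed to rTSP1. Untreated cultures and cultures with an isotype control antibody were not analysed here, so the comparison covers the antibody on top of rTSP1 and not rTSP1 itself. Nothing in the labels says that the 3 replicates of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Estimated depth was about 24800000, 27200000 and 26000000 fragments in the rTSP1 libraries and 26000000, 29400000 and 16100000 in the anti-CD36 libraries, so the third anti-CD36 library was the shallowest. All fold changes are anti-CD36 minus rTSP1 on the log2(FPKM + 1) scale, which understates changes of low genes, and adjusted p-values are from limma with n = 3 libraries per group.

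Transcripts of the antibody's target and of the ligand were close to absent. Cd36 (chromosome 5, 17781690 to 17888801, GRCm38) was listed at 0, 0.12 and 0 FPKM in the rTSP1 libraries and at 0.19, 0.17 and 0.02 FPKM with anti-CD36, or about 12 and 37 rebuilt reads per group. Thbs1 (chromosome 2, 118111876 to 118127133) was listed at 0.19, 0 and 0.09 FPKM and at 0, 0.03 and 0 FPKM. Both lay below the filter on low values and were not tested. Cd47, which encodes a second thrombospondin receptor, was at 138.9 ± 1.47 FPKM (SD, n = 3) without and 157.4 ± 3.54 FPKM with the antibody, and its log2 fold change of 0.18 ± 0.05 (SE) did not pass (adjusted p = 0.057). Of the 15 measured genes of the CD36 and thrombospondin list, 1 rose (2 adjusted over the list alone): Calr, a chaperone of the endoplasmic reticulum that also binds thrombospondin at the cell surface, by 0.35. Itgb3 (0.37) and Fabp5 (-0.21) did not pass, and the list as a whole was not called (camera adjusted p = 0.089). It was called, towards higher values, without anti-CD36 replicate 3 (adjusted p = 0.030) and with limma-voom on rebuilt reads (adjusted p = 0.030), and not with an estimated correlation (adjusted p = 0.57).

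With anti-CD36, 31 of 40 interferon response genes fell, 19 of 25 genes of the p53 and senescence list rose, and of 19 neutrophil and granule markers 12 rose and 1 fell, the last list not being called with an estimated correlation (adjusted p = 0.18). Irf7, a transcription factor that amplifies type I interferon responses, went from 35.1 ± 3.11 to 1.55 ± 0.83 FPKM. The cell cycle inhibitor gene Cdkn1a rose from 126.3 ± 3.76 to 226.2 ± 21.2 FPKM, and Ctsg, which encodes the granule protease cathepsin G, rose from 54.0 ± 11.1 to 119.6 ± 11.6 FPKM. In all, 812 of the 10758 genes tested changed, 431 higher and 381 lower with the antibody, and 118 of them had an absolute log2 fold change of at least 1. The groups did not overlap for 26.3% of the genes tested, where chance gives 10%. The first principal component held 43.5% of the variance and separated the groups. Pearson correlations between libraries were 0.985 to 0.988 within groups and 0.975 to 0.981 between groups. The number of changed genes was 357 without the filter on low values and 316 in limma without a variance trend. It was 500 without rTSP1 replicate 1, 453 without rTSP1 replicate 3, 525 without anti-CD36 replicate 1 and 521 without anti-CD36 replicate 2.

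**Figure D1:**
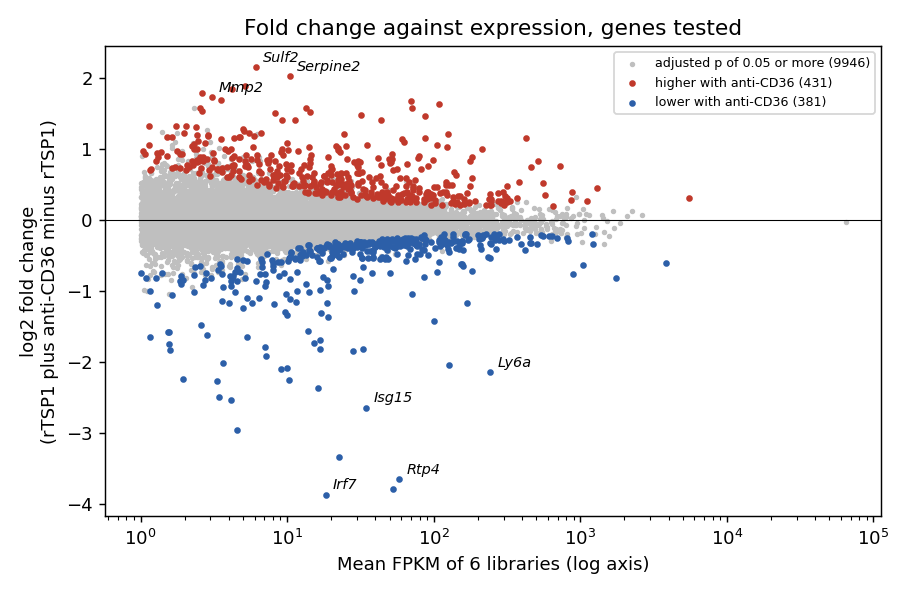
Log2 fold change (anti-CD36 minus rTSP1) of each of the 10758 genes tested against its mean FPKM over the 6 libraries, on a log axis. Red points are the 431 genes higher and blue points the 381 genes lower with anti-CD36 at an adjusted p below 0.05, and the genes with the largest decreases include Irf7, Rtp4 and Isg15.

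The interferon response list showed the largest change of any list tested. Of its 40 measured genes, 31 fell and none rose (33 fell adjusted over the list alone), with a median log2 fold change of -0.93 (camera adjusted p = 6.2e-37, and adjusted p = 0.031 with an estimated correlation). Ifi27l2a fell by 3.79 on the log2 scale, from 98.5 ± 12.2 to 6.30 ± 1.68 FPKM, and Rtp4 fell by 3.65, from 108.7 ± 13.8 to 7.77 ± 1.41 FPKM. Isg15, a ubiquitin-like modifier, fell by 2.65, from 60.3 ± 8.44 to 8.79 ± 1.32 FPKM. Usp18, which removes that modifier from proteins and restrains interferon receptor signalling, fell by 1.83. The RNA-binding antiviral genes Ifit1 and Ifit3 fell from 6.52 ± 0.25 to 0.34 ± 0.19 FPKM and from 7.71 ± 2.06 to 0.51 ± 0.41 FPKM, and Oasl2 fell by 2.25. Changes were smaller for Psmb8, a subunit of the immunoproteasome, which fell by 0.49, and Tap1, a peptide transporter for antigen presentation, which fell by 0.55. The 12 largest decreases among all genes named by the rule were Irf7 (chromosome 7, 141262706 to 141266481, log2 fold change -3.87 ± 0.21, adjusted p = 1.1e-06), Ifi27l2a, Rtp4, Ighv1-23, Oasl1, Isg15, Ifit3, Ifit1, Cox6a2, Phf11b, Oasl2 and Apol9b. Apol9b was at 3.90 FPKM on average with rTSP1 and listed at 0 in all 3 anti-CD36 libraries. Ighv1-23, an immunoglobulin variable segment, Apol9b, Oasl1 and Oasl2 belong to families of similar genes, and reads shared within a family leave their values uncertain.

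**Figure D2:**
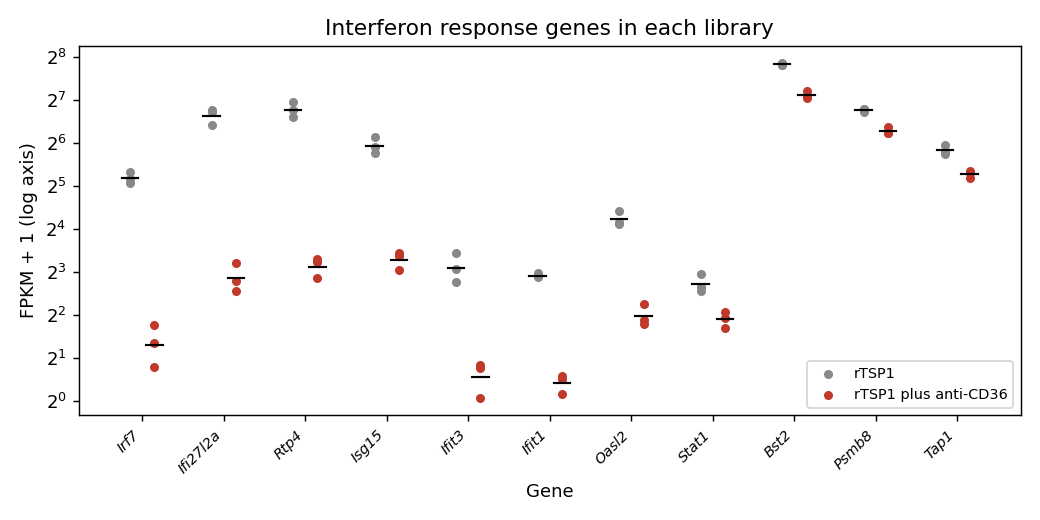
FPKM + 1, on a log axis, of 11 interferon-stimulated genes in each of the 6 libraries. Grey points are the 3 rTSP1 libraries, red points the 3 anti-CD36 libraries and bars the group means on the log scale, and the groups do not overlap for any gene drawn.

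Targets of the tumour suppressor p53 rose together. Of the 25 measured genes of the p53 and senescence list, 19 rose and none fell (23 rose adjusted over the list alone), with a median of 0.69 (camera adjusted p = 3.8e-20, and adjusted p = 0.042 with an estimated correlation). Phlda3, an inhibitor of Akt signalling, rose by 0.89 ± 0.07, Ccng1 by 0.87 ± 0.08 and Cdkn1a (chromosome 17, 29090976 to 29100727) by 0.83 ± 0.07. Ddit4l rose by 1.85, from 1.28 ± 0.59 to 7.16 ± 1.77 FPKM. Gtse1, which is in this list and in the list for mitosis, rose by 0.87. Trp53, which encodes p53, was at 106.0 FPKM without and 110.5 FPKM with the antibody (adjusted p = 0.61). No filter left 11 members higher, a filter at a mean of 5 FPKM left 12.

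Genes of the granulocyte lineage rose. Of 19 measured neutrophil and granule markers, 12 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 2.1e-10, and adjusted p = 0.18 with an estimated correlation). Csf3r, the receptor gene for granulocyte colony-stimulating factor, rose by 0.86, Prtn3, which encodes proteinase 3, by 1.06 and Ctsg by 1.15. Nkg7, which encodes a granule membrane protein, rose from 373.6 ± 38.3 to 661.3 ± 45.8 FPKM. The member that fell was Gfi1, a transcriptional repressor needed for neutrophil differentiation, with a log2 fold change of -1.02. The number of members higher was 7 in limma without a variance trend and 7 without anti-CD36 replicate 2.

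**Figure D3:**
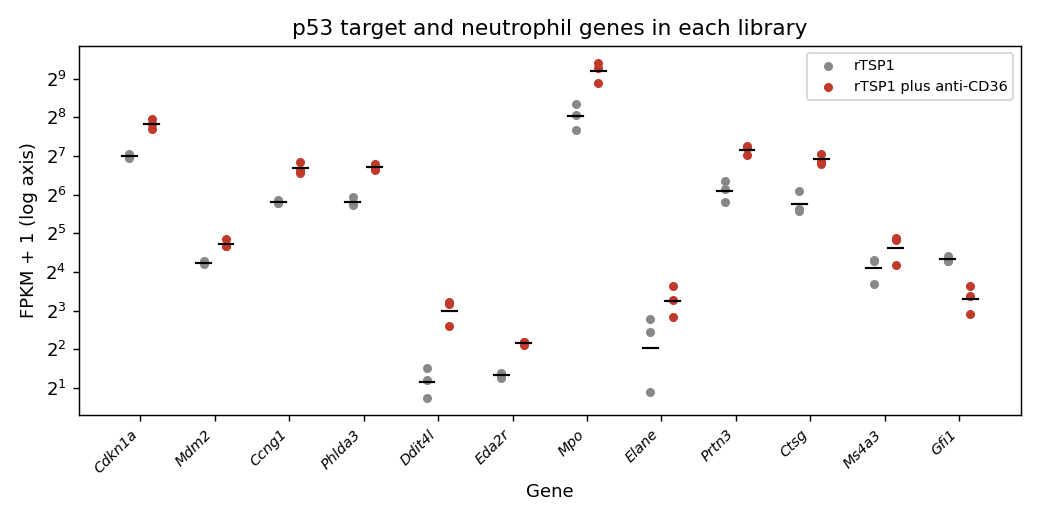
FPKM + 1, on a log axis, of 6 p53 targets and 6 neutrophil genes in each of the 6 libraries, with the 3 rTSP1 libraries in grey, the 3 anti-CD36 libraries in red and bars for the group means on the log scale. Cdkn1a, Ccng1 and Phlda3 are higher in all 3 anti-CD36 libraries, Gfi1 is lower in all 3, and the groups overlap for Ms4a3.

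Markers of other blood lineages moved too, several in both directions. Of 21 mast cell and basophil markers 7 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.50 with an estimated correlation). Mcpt8, a basophil protease, rose by 1.63, from 53.3 ± 8.68 to 165.5 ± 8.11 FPKM, Ccl9 by 1.21 and Alox5, the 5-lipoxygenase gene, by 0.86. The members that fell were Prss34 and Gata2. Among all members past the threshold the largest absolute log2 fold change was 1.65, above that of Mcpt8. Of 13 monocyte and macrophage markers 5 rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.025, and adjusted p = 0.39 with an estimated correlation). Cd68, a lysosomal membrane protein, rose by 1.58, from 34.9 ± 0.60 to 106.6 ± 6.81 FPKM, and Lyz2 by 0.75, whereas Ctss, which encodes cathepsin S, fell by 2.08. Without rTSP1 replicate 3 neither the mast cell nor the monocyte list was called, and without rTSP1 replicate 1, at equal FPKM totals or at a mean of at least 5 FPKM the monocyte list was not. Of 11 erythroid markers 5 rose and none fell (5 adjusted over the list alone; adjusted p = 7.3e-04, and adjusted p = 0.23 with an estimated correlation), led by the globin gene Hbb-bt (0.99), the metallothionein genes Mt1 (0.76) and Mt2 (0.82), which bind metals and are not specific to red cells, and Blvrb (0.79). Gata1, a transcription factor gene that is in the erythroid list as well as the eosinophil list, did not pass (0.01). Without the filter on low values the erythroid list was not called. Of 27 megakaryocyte and platelet markers 4 rose and none fell (8 rose and 4 fell adjusted over the list alone), among them Cd9 (0.24), Ppbp (0.50) and Selp (0.49), and the list was not called (adjusted p = 0.48). Of 7 lymphoid markers only Nkg7 rose (3 adjusted over the list alone; adjusted p = 0.24), and Flt3 (-0.21) did not pass. With 2 eosinophil and 3 endothelial and stromal markers measured, these lists were not tested. Siglecf rose by 0.82, Gata1 was at 0.01, and Plvap (0.57) and Tie1 (-0.01) did not pass.

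Genes that define stem cells did not move one way. Of 37 measured HSC identity and quiescence genes, 4 rose and 5 fell (5 and 6 adjusted over the list alone; adjusted p = 0.70). Ly6a, which encodes the stem cell surface marker Sca-1 and is induced by interferon, fell by 2.15, from 396.1 ± 48.0 to 90.0 ± 22.4 FPKM. Gfi1b fell by 0.42 and Cdkn1c, a cell cycle inhibitor gene active in quiescent stem cells, fell by 0.82, whereas Sult1a1 rose by 1.32. Procr (-0.37), Hlf (-0.28) and Slamf1 (-0.11) did not pass. Of 18 genes of the aged HSC list 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Aldh1a1 up by 1.03 and Nupr1 down, with a log2 fold change of -0.90, and the list was not called (adjusted p = 0.11). Of these 18 genes 8 are also in other lists, among them Mt1, Mt2, Selp and Sult1a1, which rose, so the lists are not separate evidence.

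Genes of mitosis rose modestly and nuclear genes of the respiratory chain fell modestly. Of 36 G2 and mitosis genes 7 rose and none fell (12 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 5.2e-09, and adjusted p = 0.23 with an estimated correlation). Psrc1 rose by 0.62, Ccnb2, which encodes cyclin B2, by 0.38 and Birc5, which encodes survivin, by 0.27. Of 36 S phase genes 2 rose, Rrm2 (0.49) and Tipin (0.25), and none fell (2 adjusted over the list alone; adjusted p = 0.48). Of 60 nuclear oxidative phosphorylation genes 19 fell and none rose (29 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 4.6e-09, and adjusted p = 0.25 with an estimated correlation). Cycs, which encodes cytochrome c, fell by 0.39, Ndufs6, a complex I subunit gene, by 0.36 and Atp5h, an ATP synthase subunit gene, by 0.34. In limma without a variance trend no oxidative phosphorylation gene and 2 mitosis genes passed. Leaving out rTSP1 replicate 1, rTSP1 replicate 3, anti-CD36 replicate 1, anti-CD36 replicate 2 and anti-CD36 replicate 3 left 8, 7, 9, 12 and 11 oxidative phosphorylation genes, and leaving out single libraries left 3 to 6 mitosis genes. Of 62 ribosomal protein genes 2 fell, Rpl35 (-0.42) and Rpl27 (-0.28), and none rose (2 adjusted over the list alone; camera adjusted p = 0.0010, and adjusted p = 0.64 with an estimated correlation), and this list was not called without rTSP1 replicate 3 (adjusted p = 0.12).

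**Figure D4:**
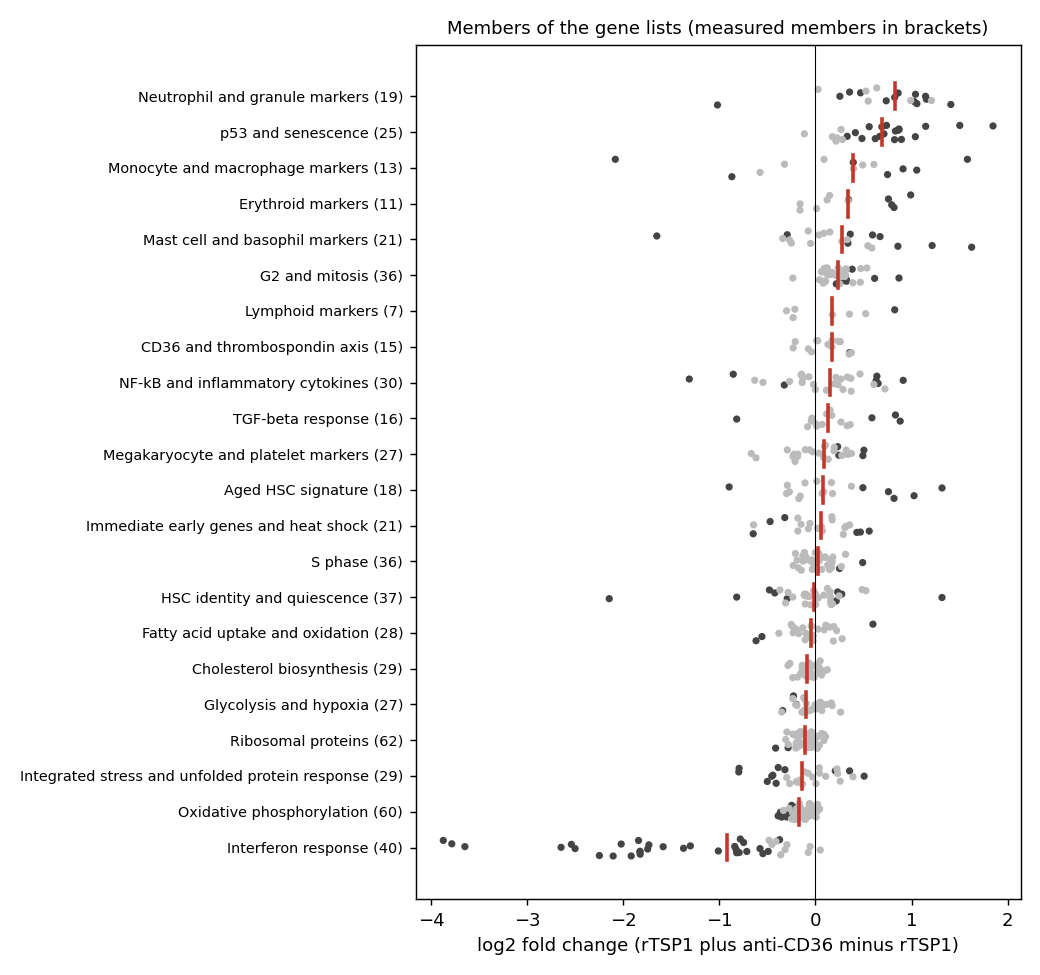
Log2 fold change (anti-CD36 minus rTSP1) of each measured member of the 22 lists tested, with dark points for members at an adjusted p below 0.05, pale points for the others and red bars for list medians. The medians run from -0.93 for the interferon response to 0.82 for neutrophil and granule markers.

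Most inflammatory, metabolic and stress lists held changes in both directions, but the glycolysis and hypoxia genes that passed all fell and no cholesterol synthesis gene passed. Of 30 NF-kB and inflammatory cytokine genes 4 rose and 3 fell (6 and 5 adjusted over the list alone; adjusted p = 0.50). The chemokine gene Ccl5 fell by 1.31 and Cxcl10, which interferon induces, fell by 0.86, whereas Nfkbia, the inhibitor of NF-kB, rose by 0.63 and Ccl4 by 0.64. Of 16 TGF-beta response genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.23 with an estimated correlation). They were Cdkn1a, the differentiation regulators Id1 (0.59) and Id2 (0.88), and Cdkn1c, which fell; without rTSP1 replicate 1 the list was not called. Of 29 genes of the integrated stress and unfolded protein responses 3 rose and 8 fell (6 and 11 adjusted over the list alone; adjusted p = 0.078). Trib3 fell by 0.80, the amino acid transporter gene Slc7a5 by 0.50 and Aldh18a1, for proline synthesis, by 0.39. Of 28 fatty acid genes Acadl (-0.62) and Eci1 (-0.56), both enzymes of beta-oxidation, fell and Plin2, which coats lipid droplets, rose by 0.60 (3 lower and 1 higher adjusted over the list alone; adjusted p = 0.32). Of 27 glycolysis and hypoxia genes 3 fell and none rose (6 adjusted over the list alone; adjusted p = 0.11), namely Mif (-0.34), Eno1 (-0.23) and Ldha (-0.20). None of 29 cholesterol synthesis genes passed over all genes or adjusted over the list alone (limma adjusted p = 0.11 for Fasn, log2 fold change -0.24), and 2 of them, Fasn and Nsdhl, had an unadjusted p below 0.05. Of 21 immediate early and heat shock genes 3 rose and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.48), with Ier3 (0.47) up and the chaperone gene Hspa8 (-0.32) down. In total 10 of the 22 lists tested were called with the preset correlation, and 2 of these, interferon response and p53 and senescence, with an estimated one.

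The 12 largest increases named by the rule lay partly outside these lists. Sulf2, an enzyme that trims heparan sulfate at the cell surface, rose by 2.15 ± 0.15 (chromosome 2, 166073089 to 166155663, adjusted p = 8.5e-06), from 1.60 ± 0.01 to 10.6 ± 1.45 FPKM. Serpine2, a protease inhibitor, rose by 2.02 ± 0.13, from 3.51 ± 0.42 to 17.3 ± 1.48 FPKM. Ephx1, an epoxide hydrolase, rose by 1.89 and Mmp2, a matrix metalloproteinase, by 1.72. Cox6b2, a cytochrome c oxidase subunit known from testis, rose by 1.68, from 32.7 ± 2.34 to 107.4 ± 12.7 FPKM. Pglyrp1, a granule protein that binds bacterial cell wall, rose by 1.57, Cd300c by 1.57 and Slpi, a protease inhibitor of myeloid cells, by 1.51. The others were Ddit4l, Mcpt8, Cd68 and Trav14n-3, a T cell receptor segment with near-identical copies whose value is uncertain for that reason. Cox6a2, a cytochrome c oxidase subunit known from muscle, was among the 12 largest decreases and fell by 2.36, from 27.7 ± 2.21 to 4.73 ± 1.75 FPKM.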

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

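Limma-voom on rebuilt reads, camera with a variance trend and the counts of list members under each setting were chosen after the data were seen. Of the 85 named genes past the threshold, none changed direction under a setting that tested it; a mean of at least 5 FPKM left 73 of them tested. The calls lost were 16 without the filter, 27 in limma without a variance trend and at most 11 when a library was left out (rTSP1 replicate 3). Without the filter, where 18349 genes were tested, 357 genes changed (203 higher, 154 lower; 322 of them among the reported ones), and 11 p53, 7 oxidative phosphorylation and 4 mitosis members passed. At a mean of at least 5 FPKM, 12 p53 members passed, since fewer were tested. In limma without a variance trend 316 genes changed (192 higher, 124 lower; 297 shared), with 7 neutrophil, 0 oxidative phosphorylation and 2 mitosis members; the cause was not tested. Requiring an absolute log2 fold change of at least 1 left 118 genes. With an estimated correlation 2 lists were called, with fry 9 and with a variance trend in camera 12. Fry called the lymphoid list (fry adjusted p = 0.024), which was not called as reported. It did not call the ribosomal protein list (fry adjusted p = 0.26) or the mast cell and basophil list (fry adjusted p = 0.056). Voom called 683 genes, with 10 oxidative phosphorylation members lower, and 15 lists. The CD36 and thrombospondin and the aged HSC lists, not called as reported, were called with voom and without anti-CD36 replicate 3, cholesterol synthesis with voom, without the filter and without rTSP1 replicate 2, glycolysis with voom and without the filter, and the integrated stress list with voom, without rTSP1 replicate 1 and without anti-CD36 replicate 2.

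Leaving out each library gave 453 to 582 changed genes, 248 to 334 higher and 190 to 273 lower, with 28 to 30 interferon members lower, 13 to 15 p53, 7 to 10 neutrophil and 3 to 6 mitosis members higher, 7 to 14 oxidative phosphorylation members lower and 7 to 12 lists called. These counts of genes and members were all below the reported ones, and the number of lists called was above the reported 10 in 3 of the 6 fits. Each fit had 1 library fewer than the reported one, and the cause was not tested apart from that. The median of the interferon list lay between -0.89 and -1.01 in these fits. Replicate numbers did not pair the samples: same-numbered libraries had deviation correlations of -0.016, -0.016 and 0.008. A fit with the replicate block gave 694 changed genes (386 higher, 308 lower), 10 lists and 9 oxidative phosphorylation members. Other pseudocounts and scalings gave 757 to 814 genes. Gata1 (0.01 ± 0.16, SE) and Tie1 (-0.01 ± 0.09), which had not passed, changed sign under some settings. All their values given next were smaller in size than these SEs. Gata1 was at -0.021 with array weights, -0.01 without rTSP1 replicate 2, -0.10 without rTSP1 replicate 3 and -0.13 without anti-CD36 replicate 1, and its highest value, of unchanged sign, was 0.149 without rTSP1 replicate 1. Tie1 was at 0.0057 after quantile normalization, 0.015 at equal FPKM totals, 0.055 without rTSP1 replicate 1 and 0.04 without anti-CD36 replicate 2, and its lowest value, of unchanged sign, was -0.078 without rTSP1 replicate 2; the cause was not tested. Apart from limma-voom on rebuilt reads, tests made for counts were not run, because the deposited values are FPKM. How depth limits calls of low genes was not tested.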

Other observations

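Members of 2 further gene groups passed the threshold; the groups were chosen after the values were seen, so no test of them as groups is given. Of 23 measured genes of MHC class I presentation, 18 fell and none rose, and 3 of the 23 are also in the interferon list. H2-D1 went from 1266 ± 25.8 to 816.7 ± 32.6 FPKM and B2m, the light chain of class I molecules, from 4627 ± 151.8 to 3027 ± 82.9 FPKM. H2-Q6 and H2-Q7 fell as well, but share reads with near-identical copies. Of 26 measured targets of NRF2, a transcription factor of the oxidative stress response, 15 rose and 1 fell, G6pdx. Nqo1 went from 44.6 ± 1.76 to 130.8 ± 53.5 FPKM, Srxn1 from 39.9 ± 1.26 to 65.6 ± 5.78 FPKM, and Cat, which encodes catalase, from 147.7 ± 7.64 to 205.0 ± 5.43 FPKM.

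The tests below on splits, plasmacytoid dendritic cells, library scaling and cell shares were chosen after the result was seen, and those on the shallower library and on length and GC content before. Among the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real one, the real split itself, with 812 genes, and the highest of the others gave 0. With 10 splits the share cannot go under 0.1. Every other split mixes the treatments, which adds their difference to the spread within groups, so few calls could come from it. The splits cannot decide on chance for that reason.

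The interferon decrease did not rest on the shallower library: without anti-CD36 replicate 3 the median of the 40 genes was -1.01. Whether plasmacytoid dendritic cells, which make much interferon, were lost cannot be told apart from a change within cells. By the labels the cells were sorted as stem or stem and progenitor cells. Which gate was used was not settled, so whether it removed mature cells of that type is not known. Of the 9 markers measured, of 24, 7 had a positive and 2 a negative fold change, with a median of 0.30. Cd300c (1.57) and Sell (0.67) rose, and Cox6a2 fell from 27.7 ± 2.21 to 4.73 ± 1.75 FPKM. Irf8 (0.09) and Tcf4 (0.01), both close to the filter at a mean of 1 FPKM, did not pass. The markers did not fall as a set, but those that passed moved both ways, so they do not decide on such a loss. An effect of the antibody other than blocking CD36 stays open as well, because no isotype control was analysed here. Blocking of CD36, the difference the design names, also stays open and was not tested apart from these, and Cd36 itself was listed at no more than 0.19 FPKM in any library.

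Nuclear oxidative phosphorylation genes and mitochondrially encoded mRNAs, the latter chosen after their values were seen, moved apart. Of 13 mitochondrial mRNAs 9 were measured, of which 7 rose and none fell, with mt-Nd1 going from 453.9 ± 29.0 to 652.6 ± 40.2 FPKM. Their levels were very unequal: mt-Co3 was at 2.67 FPKM without and 3.53 FPKM with the antibody, mt-Co1 at 1099 and 1504 FPKM. Whether reads of some of these genes were lost or placed elsewhere was not tested, so their values are uncertain. The medians lay 0.69 apart on the log2 scale, and a scaling factor per library, which moves all genes alike, cannot open such a gap; at equal FPKM totals the medians were 0.55 and -0.14. After a smooth trend on length, GC content and expression was removed, the nuclear list's median was -0.14, against -0.17 before. That median lay at percentile 0 of 10000 random lists matched on expression. The random lists drew genes one by one, whereas genes of this list vary together (estimated correlation 0.17), so the percentile can overstate how unusual the median is. The nuclear decrease is small, 0 of its members passed in limma without a variance trend, and RNA quality and other explanations were not tested.

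Of the lineage lists called, the neutrophil list had the highest median, and none was called with an estimated correlation (adjusted p = 0.18 for neutrophil, 0.23 for erythroid, 0.39 for monocyte and 0.50 for mast cell and basophil markers). The lineage lists did not move alike. This cannot decide whether a smaller share of primitive cells was the whole cause, because some lineage markers are also members of the stem cell lists. Of the 27 measured megakaryocyte markers 6 are also in other lists, among them Mpl in the HSC identity list and Selp in the aged HSC list. The neutrophil median lay 0.74 above the megakaryocyte (permutation p = 1e-05, the smallest the permutations can give), 0.82 above the lymphoid with Nkg7, a member of both lists, left out of both (adjusted permutation p = 0.0072), 0.55 above the mast cell and basophil (adjusted permutation p = 0.0085) and 0.48 above the erythroid median (adjusted permutation p = 0.045), and 0.43 above the monocyte median, which did not pass (adjusted permutation p = 0.070), so 4 of 5 differences passed over genes, which are not independent. Of the 8 most abundant neutrophil list members 8 had a positive fold change, but Anxa1 (0.03, adjusted p = 0.90) did not pass, and Calr and Gstm1 are not specific to granulocytes. A larger share of granulocyte-committed cells and higher expression within cells both predict this and cannot be told apart, in cells that the labels say were sorted as stem or stem and progenitor cells.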
